A study of Mus musculus with 2 samples.

How the data were processed

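RNA was measured by sequencing in 2 mammary tumor samples from MMTV-PyVT mice, 1 from a mouse given the vehicle dimethyl sulfoxide (DMSO) and 1 from a mouse given cyanidin-3-glucoside (C3G). Per the labels' protocols, RNA was purified with RNeasy Plus columns and libraries were made with the TruSeq RNA kit, version 2, a kit that selects polyadenylated RNA and does not mark the strand. Reads from overlapping or antisense genes could therefore not be told apart. Per the submitters' processing notes, the tools used on the reads were FastQC, MultiQC, Trimmomatic 0.38 and featureCounts 2.0.0, with the mouse genome build mm10. The aligner was not given in the sources used here, nor was the treatment of reads that fit several genes equally well. The deposited values are in TPM (transcript abundance scaled by gene length to a fixed total per library), which the authors set out for 55536 Ensembl genes with 1 column per library. Each column summed to 1000000 TPM.

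All 55536 identifiers matched GENCODE mouse release M21, from which gene symbols, positions, exon-union lengths and GC content were taken. TPM keeps no depth by itself, but the product of TPM and exon-union length was a whole multiple of 1 step per library for 100% of the values above 0, within a tolerance of 0.01 of a step. Taking 1 step as 1 counted read (or read pair, which the values do not separate) gave 12192275 reads for the DMSO library and 16081110 for the C3G library. The main ratios and calls came from the TPM values. These reads gave the intervals, the read shares, a later minimum of 50 reads, a later thinning to equal depth and the depth of the simulated libraries. No count test was run. Each fold between the libraries has an exact conditional 95% interval from its reads. Such intervals, and the Wilson 95% intervals of read shares, cover counting error only, because reads without molecular identifiers are not independent molecules and because 1 tumor per group gives no spread between animals. Among genes with a mean of 5 to 10 TPM over the 2 libraries, the median was 110 reads in the DMSO library. A typical interval of the fold reached 1.29-fold to either side of the estimate. At a mean of 50 to 100 TPM the median was 1000 reads in the DMSO library and the interval reached 1.09-fold. A count of 3 reads, taken as the floor of detection, corresponded to 0.277 TPM in the DMSO library and 0.218 TPM in the C3G library. Both values are for a gene of 1 assumed length, not of the measured median length.

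With 1 library per group no gene was tested and no p-value was computed. The log2 ratio of each gene was log2((C3G TPM + 1)/(DMSO TPM + 1)), a scale that understates the change of low genes. Folds in the text are plain ratios of TPM. A gene was called higher or lower by size when its higher TPM was at least 5 and its log2 ratio was at least 1 in size. The genes named in the text followed a rule. Among genes with a higher TPM of at least 10, leaving out predicted genes and antigen receptor V, D and J segments, the 12 with the highest and the 12 with the lowest log2 ratio were named, together with up to 4 members per described list that had the largest log2 ratio in size and a higher TPM of at least 5. The 39 gene lists, the rule, the thresholds and most alternatives were fixed before the data were examined. The same rule among genes with at least 50 reads in both libraries together was added after the data were seen, as were further lists that are named as such. Genes that share a symbol were represented by the identifier with the higher mean TPM.

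A gene list was summarised by the median log2 ratio of its members with a mean TPM of at least 1, of which the table held 17468 genes in all. That median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 95% of its random lists. This placement describes the 2 libraries and is not a p-value for the treatment.

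The procedure was tested on simulated data in which counts were drawn for the C3G against DMSO comparison over all 55536 genes, 200 of them changed. Counting noise alone led to a call by size for 179 of 12192 unchanged genes (1.47%), and for 2 of 11429 when at least 50 reads were required. Genes raised 3-fold were called in 100% of cases and genes lowered 3-fold in 97.5%, while none raised 1.5-fold was called. For genes changed 6-fold the shares were 100% upwards and 90% downwards. Of 300 random lists of 15 genes with no shift, 5.67% stood apart, and of 300 with a shift of 0.5 on the log2 scale 95.7% did.

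The alternatives changed 1 choice at a time. They were a pseudocount of 0.1 or 5, and no filter on low values or a stricter one. The stricter filter was a mean TPM of 5, and a higher TPM of 20 for the calls by size. Log2 ratios were also centred on the median of genes with a mean TPM of at least 10. TPM was rescaled without mitochondrially encoded genes and the 50 most abundant genes. In another rescaling the milk, adipocyte, skeletal muscle, skin and red blood cell lists were left out. Others were a log2 ratio of 2 as the size threshold, the mean in place of a list's median, and each list without its most extreme member. After the data were seen, thinning the C3G reads to the DMSO total, removing lowess trends on gene length and GC content (span 0.3), matching random lists on length too and requiring 50 reads were added. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No column of the table was left out.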

Results

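The study asked how cyanidin-3-glucoside, an anthocyanin pigment of berries and other plants, affects mammary tumors that arise in MMTV-PyVT mice, which express the polyoma virus middle T antigen in the mammary epithelium and develop tumors there. Treatment with C3G or DMSO began when the ducts showed hyperplasia, and tumors were taken once they had grown to a set burden. Gene expression was measured by RNA sequencing in 1 tumor library of each group. The DMSO library held 12192275 gene-assigned reads, recovered from its TPM values, and the C3G library 16081110. Of 55536 genes, 23746 were above 0 in the DMSO tumor and 24656 in the C3G tumor, and 17288 and 17370 reached 1 TPM. With 1 tumor per group, no value below has a replicate check. Each interval in parentheses after a fold is a 95% interval for counting error alone, and differences between the libraries cannot be separated from differences between individual mice.

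Fat cell, endothelial and cell cycle lists stood above their random lists in the C3G tumor, and lymphocyte, antigen presentation and interferon lists below, under all alternatives run on them. By size, 396 genes were higher and 550 lower in the C3G tumor among 12780 genes with a higher TPM of at least 5. With at least 50 reads per gene these counts were 218 and 312. The ethanol-inducible cytochrome P450 gene Cyp2e1 (mm10 chromosome 7, 140763739 to 140774987) stood at 0.962 TPM in the DMSO tumor and 31.1 TPM in the C3G tumor, a ratio of 32.3 (16.9 to 71.3). At the other end, Hspa1a, an inducible heat shock protein of the Hsp70 family (chromosome 17, 34969190 to 34972156), stood at 118 TPM with DMSO and 8.40 TPM with C3G, 14.1-fold lower (11.8 to 16.9). Its near-identical neighbour Hspa1b was 3.56-fold lower (3.33 to 3.81), at 270 against 76.0 TPM, and the split of reads between these genes is uncertain.

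Among genes with at least 50 reads, the 12 highest also held the fat cell genes Retn, Car3, Fabp4, Cidec, Cfd and Adipoq. The antimicrobial peptide gene Defb1 had 1 read in the DMSO library and 59 in the C3G library (0.265 and 12.3 TPM). Wfdc21 stood at 2.13 and 30.2 TPM, and the acute phase gene Orm1 at 2.08 and 22.8 TPM, a ratio of 10.9 (5.11 to 27.9). The replication-dependent histone genes Hist1h1b and Hist1h2ao were 9.86-fold (3.62 to 37.6) and 6.05-fold (2.58 to 17.3) higher, the latter uncertain because its family members are near-identical. The 12 lowest held the fibrinogen chain genes Fgb and Fgg, Fgb at 14.8 against 1.29 TPM and Fgg at 32.2 against 6.09 TPM. They also held the nonclassical MHC class I genes H2-Q6 (560 against 80.2 TPM), H2-Q7 (114 against 23.1 TPM) and H2-M2 (18.0 against 3.17 TPM), whose shared sequence makes the assignment of reads uncertain. Igkc, the immunoglobulin kappa constant region, was 5.47-fold lower (3.76 to 8.14). The remaining genes of the 12 were Hspa1a, the cornified envelope gene Sprr1a (31.8 against 3.61 TPM), Prol1 (22.6 against 2.35 TPM), Fam25c (85.9 against 11.6 TPM), the enamel protein gene Amtn (28.4 against 4.81 TPM) and Rpl39l (34.4 against 6.35 TPM).

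**Figure D1:**
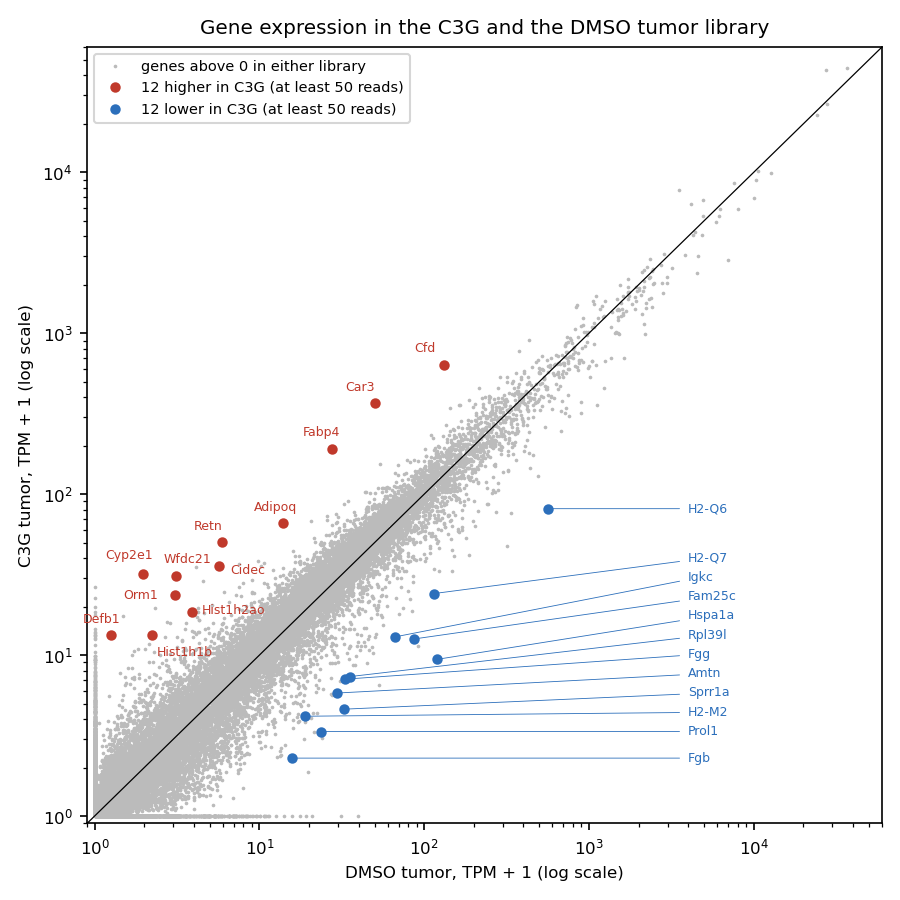
Expression of each gene above 0 in either library, as TPM + 1 on log axes, with the DMSO tumor on the x axis and the C3G tumor on the y axis. Each grey point is a gene and the line marks equal values. The 12 genes highest (red) and lowest (blue) in the C3G tumor among those with at least 50 reads are named, and 6 fat cell genes lie among the red points, with Cfd at 130 and 637 TPM.

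Without that minimum, 8 of the 12 highest and 5 of the 12 lowest were microRNA, small nucleolar RNA and mitochondrial transfer RNA loci, which are too short for libraries of this kind to measure well. They were Mir186, Mir7059, mt-Ty, Mir5709, Mir1929, Snord53, Snord42b and Mir6955 on the higher side and Mir99b, Mir6946, Mir7030, Mir200a and mt-Ts1 on the lower side. They rested on 3 to 14 reads in the higher library, and 12 of the 13 had no read in the other, so no fold is given. The other 4 highest were Cyp2e1, Defb1, Wfdc21 and Hist1h2ap, the last with 1 read against 44. The other 7 lowest were Hspa1a, Sprr1a, Prol1, Fgb, H2-Q6, Fam25c and Igkc.

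Over 17468 genes with a mean TPM of at least 1, the correlation of log2 values between the tumors was 0.94 across genes, which are not independent replicates. The median log2 ratio of these genes was 0.10, and centring on genes with a mean TPM of at least 10 shifted all log2 ratios by 0.12. Centred in that way, 298 genes were higher and 663 lower by size, so that 31.0% of calls were upward in place of 41.9%. Longer genes had higher ratios. The median log2 ratio was -0.20 in the shortest eighth of 12107 genes with a mean TPM of at least 5 and 0.21 in the longest eighth, and Spearman's correlation of length with log2 ratio across genes was 0.23. With length and GC trends removed, 488 genes were higher and 420 lower, 53.7% of calls upward. Of the 39 gene lists, 7 stood above their random lists, 10 below and 22 inside. For lists of independently drawn genes 1.95 outside would be expected. Genes of 1 cell type or pathway can vary together, so that number is no measure of chance for these lists. Of the 17 lists that stood apart, 15 did so under all alternatives run on them.

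**Figure D2:**
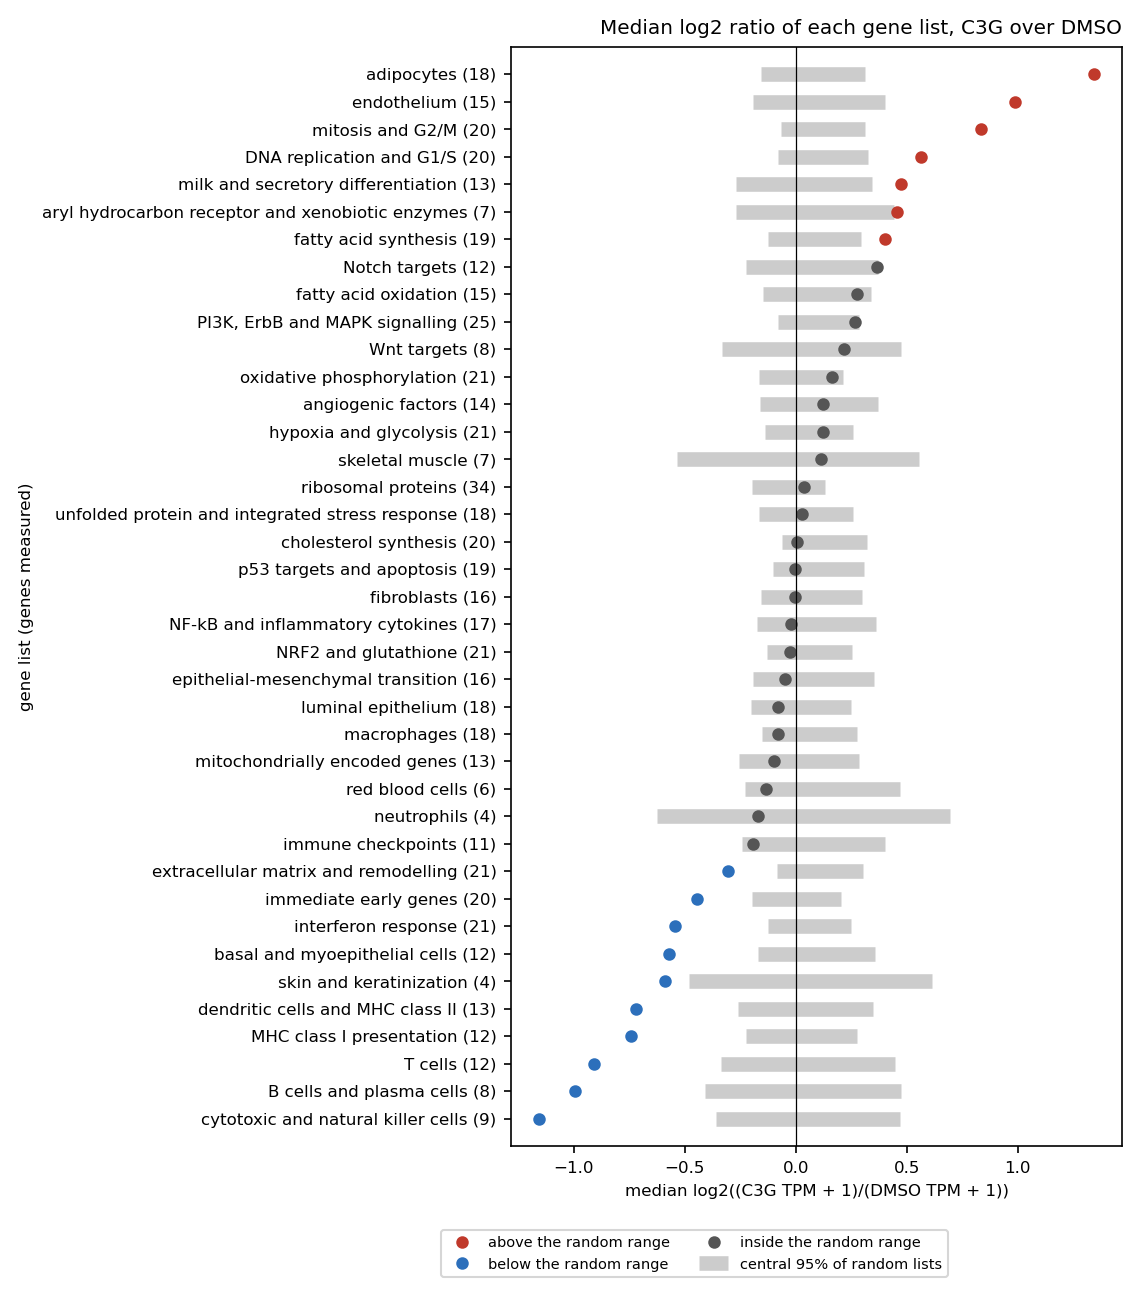
Median log2 ratio of the measured genes of each of 39 lists (x axis, C3G over DMSO; number of genes in parentheses on the y axis), with grey bars for the central 95% of 10000 matched random lists. Red and blue points lie above and below their bars, from adipocytes at 1.34 to cytotoxic and natural killer cells at -1.16.

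Lymphocyte genes were lower in the C3G tumor. All 12 measured T cell genes, of 18 listed, had log2 ratios below 0, with a median of -0.91 against a random range of -0.34 to 0.45, and 3 were lower by size. Cd2, an adhesion receptor of T cells, stood at 7.02 TPM with DMSO and 1.15 TPM with C3G, 6.11-fold lower (3.15 to 13.0). The T cell receptor constant region genes Trbc2 and Trac were 3.51-fold (2.28 to 5.52) and 2.82-fold (1.58 to 5.22) lower, and Trbc1, at 12.9 against 6.07 TPM, fell short of the size threshold. Reads of Trbc1 and Trbc2 can be shared. Of 15 listed cytotoxic and natural killer cell genes 9 were measured, and all 9 were below 0, with a median of -1.16 (random range -0.36 to 0.47) and 4 lower by size. These were the chemokines Xcl1, 4.34-fold lower (2.36 to 8.53), and Ccl5, 3.01-fold lower (2.13 to 4.31), the granule protein gene Nkg7, 3.30-fold lower (1.93 to 5.83), and the granzyme gene Gzma, at 6.88 against 2.53 TPM. Of 16 listed B cell and plasma cell genes 8 were measured, and 3 were lower by size, Igkc, the B cell coactivator Pou2af1 (6.79 against 2.36 TPM) and the immunoglobulin A heavy chain gene Igha (7.43 against 2.86 TPM). The median was -0.99 (random range -0.41 to 0.48), while the immunoglobulin M gene Ighm stood at 50.3 against 43.9 TPM. Many of these genes rest on few reads, as with 53 against 11 reads for Cd2, and the size of the medians depended on the treatment of low values. With a pseudocount of 5 they were -0.42 for T cells, -0.45 for cytotoxic cells and -0.41 for B cells, and with no filter on low values -0.44 for all 15 cytotoxic genes and -0.27 for all 16 B cell genes, each still below its random lists. In the same C3G library the adipocyte median was 1.34, and ribosomal RNA loci took 0.654% of reads against 0.308% with DMSO.

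Antigen presentation and interferon genes were lower as well. All 12 MHC class I presentation genes had log2 ratios below 0, with a median of -0.74 (random range -0.22 to 0.28) and 4 lower by size. B2m, the invariant light chain of MHC class I (chromosome 2, 122147686 to 122153083), stood at 6971 TPM in the DMSO tumor and 2849 TPM in the C3G tumor, 2.45-fold lower (2.40 to 2.50). The class I heavy chain genes H2-K1 and H2-Q4 were 2.23-fold (2.18 to 2.27) and 2.63-fold (2.51 to 2.76) lower, and the immunoproteasome subunit gene Psmb8 was 2.14-fold lower (1.97 to 2.31). All 13 dendritic cell and MHC class II genes were below 0, with a median of -0.72 (random range -0.26 to 0.35) and 3 lower by size. The class II chain H2-Eb1 was at 758 against 306 TPM, the invariant chain Cd74 at 1620 against 697 TPM and H2-Aa at 399 against 185 TPM, while H2-Ab1 at 422 against 214 TPM fell just short of the threshold. With a pseudocount of 5 the median of this list was -0.37, still below its random lists. Of 21 interferon response genes, 20 were below 0 and 4 were lower by size, with a median of -0.54 (random range -0.12 to 0.25). Ifit3 was 2.32-fold lower (2.17 to 2.48), Oasl2 2.14-fold (2.04 to 2.24), the guanylate-binding protein gene Gbp2 2.14-fold (1.97 to 2.34) and the chemokine Cxcl9 2.49-fold (1.93 to 3.24). Immediate early genes were lower in the same library, with a median of -0.45.

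Other immune lists did not stand apart. Macrophage genes had a median of -0.08 (random range -0.15 to 0.28) with none of 18 called by size, and the members with the largest ratios were the scavenger receptor Cd163 (4.90 against 8.83 TPM), Aif1 (70.5 against 44.4 TPM), Trem2 (7.74 against 12.1 TPM) and Arg1 (143 against 181 TPM). The 4 measured neutrophil genes had a median of -0.17. The immune checkpoint list had a median of -0.19, at the edge of its random range of -0.24 to 0.40, with none of 11 genes called. It stood below its random lists under 4 of the alternatives. The tryptophan-degrading enzyme Ido1 in that list stood at 27.3 against 16.4 TPM. For NF-kB targets and inflammatory cytokines the median was -0.02 and the mean 0.26, which differ in sign. Of its 17 genes 3 were higher by size, the neutrophil-attracting chemokine Cxcl2, 5.07-fold (2.87 to 9.65), the cytokine Il1b, 2.46-fold (1.79 to 3.43), and the monocyte-attracting chemokine Ccl2, 2.19-fold (1.61 to 3.01).

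**Figure D3:**
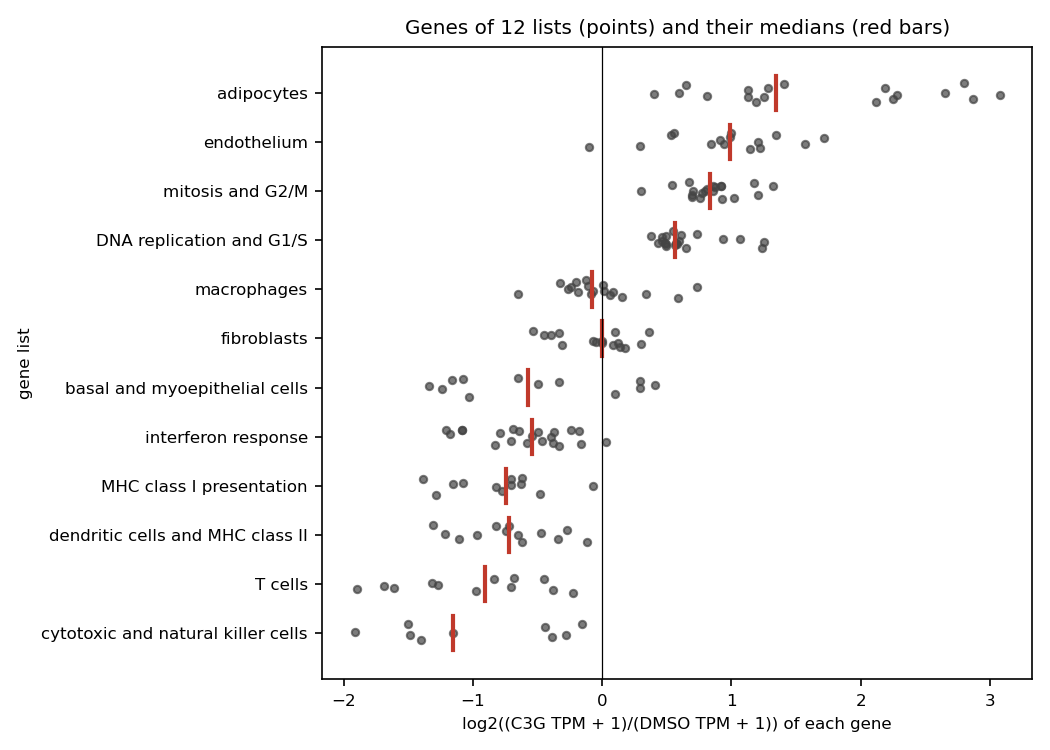
Log2 ratio of each measured gene (points; x axis, C3G over DMSO) in 12 of the lists (y axis), with red bars for the medians. Cell cycle genes all lie above 0 and T cell genes all below 0, while macrophage and fibroblast genes lie on both sides of 0, with medians of -0.08 and -0.00.

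Cell cycle genes were higher in the C3G tumor. All 20 genes of mitosis and G2/M had log2 ratios above 0, with a median of 0.84 (random range -0.07 to 0.31), and 4 were higher by size. Cyclin B1 (Ccnb1), which drives entry into mitosis, stood at 12.9 against 33.6 TPM, 2.62-fold higher (2.26 to 3.04). Cdc20, an activator of the anaphase-promoting complex, was 2.34-fold higher (2.07 to 2.64), cyclin A2 (Ccna2) 2.31-fold (2.08 to 2.56) and the mitotic kinase Plk1 2.08-fold (1.75 to 2.49). All 20 genes of DNA replication and G1/S were above 0 too, with a median of 0.56 (random range -0.08 to 0.33) and 3 higher by size. These were the replicative helicase subunit Mcm5, 2.46-fold (2.15 to 2.82), the ribonucleotide reductase subunit Rrm2, 2.39-fold (2.16 to 2.65), and Uhrf1, 2.14-fold (1.91 to 2.40), which maintains DNA methylation. Cdc6, a replication licensing factor, stood at 3.35 against 7.31 TPM. The C3G library, in which these genes were higher, also had higher endothelial genes, with a median of 0.99, and higher adipocyte genes.

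Fat cell genes were the list with the highest median. All 18 measured adipocyte genes were above 0, 11 were higher by size, and the median was 1.34 (random range -0.16 to 0.31), or 2.16 under the stricter filter on low values. Resistin (Retn), an adipocyte hormone, stood at 4.97 TPM with DMSO and 49.3 TPM with C3G, 9.93-fold higher (6.998 to 14.5). Car3, an abundant carbonic anhydrase of fat and muscle, was 7.43-fold higher (6.83 to 8.08), the fatty acid carrier Fabp4 7.18-fold (6.55 to 7.88) and the lipid droplet gene Cidec 7.41-fold (5.30 to 10.6). Adipsin (Cfd) and adiponectin (Adipoq) were 4.90-fold (4.46 to 5.39) and 5.04-fold (3.96 to 6.50) higher. Fatty acid synthesis genes had a median of 0.40 (random range -0.12 to 0.29), with 18 of 19 above 0 and only Dgat2, which completes triglyceride synthesis, higher by size at 4.04 against 10.4 TPM. Acly, which makes acetyl-CoA from citrate, stood at 80.8 against 157 TPM, Agpat2 at 34.0 against 56.2 TPM and Dgat1 at 29.2 against 46.0 TPM. Fatty acid oxidation genes, with a median of 0.27, and cholesterol synthesis genes, with a median of 0.01, lay inside their random ranges. In the same library endothelial genes had a median of 0.99 and ribosomal RNA loci took 0.654% of reads against 0.308% with DMSO.

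Endothelial genes were higher in the C3G tumor. Of 15 measured genes 14 were above 0 and 6 were higher by size, with a median of 0.99 (random range -0.19 to 0.40), or 0.64 with a pseudocount of 5. The tight junction gene Cldn5 stood at 2.93 against 11.95 TPM, 4.08-fold higher (2.44 to 7.18). The receptor genes Tie1 and Tek were 3.83-fold (2.81 to 5.32) and 3.05-fold (2.12 to 4.48) higher, and the adhesion gene Pecam1 2.78-fold (2.35 to 3.31). Angiogenic factors lay inside their range, with a median of 0.12 and none of 14 called by size; the peptide Apln stood at 3.74 against 8.32 TPM, Hif1a at 28.4 against 43.3 TPM, Pgf at 26.0 against 17.8 TPM and Nrp1 at 8.96 against 6.45 TPM. Fat cell genes were higher in the same library, with the median of 1.34 given above.

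Basal and myoepithelial genes were lower in the C3G tumor as a list, with a median of -0.57 (random range -0.17 to 0.36), 8 of 12 below 0 and 5 lower by size. Those 5 are known from smooth muscle contraction. Calponin (Cnn1) stood at 108 against 42.2 TPM, 2.57-fold lower (2.33 to 2.82), the smooth muscle myosin Myh11 was 2.40-fold lower (2.26 to 2.55), smooth muscle actin Acta2 2.24-fold (2.15 to 2.33), Tagln 2.37-fold (1.64 to 3.47) and Mylk 2.07-fold (1.97 to 2.18). The other 7 members, named after their values were seen, went both ways. Krt17 (33.2 against 20.8 TPM), Krt14 (83.7 against 66.0 TPM) and Oxtr (39.5 against 27.7 TPM) were below 0, and Krt5 (36.2 against 48.4 TPM), Trp63 (11.9 against 14.9 TPM), Krt15 and Procr were above 0. Luminal epithelial genes had a median of -0.08 (random range -0.20 to 0.25) and did not stand apart, although Krt19 was 2.75-fold lower (2.63 to 2.89) and the luminal transcription factor Foxa1 2.56-fold lower (2.08 to 3.17). Prom1 stood at 31.8 against 53.7 TPM and Krt18 at 2824 against 1769 TPM. Milk and secretory genes were higher as a list, with a median of 0.47 (random range -0.27 to 0.34), 11 of 13 measured genes above 0 and 2 higher by size. The list named 16 genes, of which Csn2, Glycam1 and Olah did not reach a mean of 1 TPM. Its middle member was the casein gene Csn1s1, at 3.14 against 4.75 TPM. The median was 0.26 with a pseudocount of 5, still above the random lists. The most abundant member, the casein gene Csn3, was not higher, at 10598 against 10186 TPM. Lalba, the next most abundant, stood at 4909 against 6700 TPM. The amino acid oxidase gene Lao1 was 5.12-fold higher (3.57 to 7.53) and whey acidic protein (Wap) 2.77-fold (2.23 to 3.46), while Xdh and Aldoc were 1.65-fold (1.57 to 1.73) and 1.61-fold (1.55 to 1.68) higher. The same C3G library had an adipocyte median of 1.34, an endothelial median of 0.99 and an immediate early gene median of -0.45, with 0.654% of reads in ribosomal RNA loci against 0.308% with DMSO.

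Fibroblast genes had a median of -0.00, with 7 above and 9 below 0, and none of 16 was called by size. The largest ratios were all below 0. They were those of the most abundant member, Col1a1 (587 against 404 TPM), Pi16 (16.2 against 11.6 TPM), Col1a2 (302 against 230 TPM) and Dcn (183 against 145 TPM). Col3a1, named outside the rule, stood at 326 against 325 TPM. Extracellular matrix and remodelling genes had a median of -0.30 (random range -0.09 to 0.30), with 15 of 21 below 0 and none called by size. The membrane protease Mmp14 stood at 106 against 56.1 TPM, the basement membrane collagen Col4a2 at 99.5 against 53.6 TPM, Timp3 at 28.3 against 18.1 TPM and Mmp11 at 3.99 against 7.08 TPM. In the same C3G library the medians were 1.34 for adipocyte, 0.99 for endothelial and -0.45 for immediate early genes, and ribosomal RNA loci took 0.654% of reads against 0.308% with DMSO. Genes of epithelial-mesenchymal transition lay inside their range, with a median of -0.05. Of 4 measured skin and keratinization genes all were below 0, with a median of -0.59 (random range -0.48 to 0.62), and Sprr1a alone was lower by size. Without Sprr1a, or with no filter on low values (median -0.03 over 9 genes), the list lay inside its range. The mean of the 4 genes was -1.01. The other large ratios were Sbsn at 23.2 against 14.9 TPM and Krt10 at 8.29 against 5.25 TPM. Skeletal muscle genes had a median of 0.12.

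Genes of the antioxidant regulator NRF2 and of glutathione metabolism went both ways, 10 above and 11 below 0, with a median of -0.03 (random range -0.13 to 0.25) and none of 21 called by size. The largest ratios were those of Txnrd1 (37.6 against 58.5 TPM), Sod1 (149 against 98.4 TPM), Gsr (85.3 against 57.8 TPM) and Gclm (22.0 against 32.7 TPM). Targets of p53 and apoptosis genes went both ways as well, 9 above and 10 below 0, with a median of -0.00 and none of 19 called. Changes of 1.5-fold lie under the size threshold. The aryl hydrocarbon receptor and xenobiotic enzyme list stood just above its range, with a median of 0.45 (random range -0.27 to 0.44). Its 7 measured genes included Cyp2e1, which is not a classical target of that receptor, Cyp1b1 (3.67 against 8.97 TPM, 2.44-fold higher, 1.93 to 3.12), Tiparp (10.2 against 16.3 TPM) and Ahr (38.7 against 53.4 TPM). Without Cyp2e1 the median was 0.27 and lay inside the range, as did the median of 0.08 over 12 genes with no filter on low values, while the mean of the 7 genes was 0.86.

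The remaining signalling, metabolic and stress response lists lay inside their ranges. Their medians were 0.27 for PI3K, ErbB and MAPK signalling, 0.22 for Wnt targets and 0.37 for Notch targets (upper bound of the random range 0.37). The last 2 lists also held pathway members that are not targets, such as the ligand Wnt4 and the receptor Notch1. Their medians therefore do not read target genes alone. For hypoxia and glycolysis the median was 0.12, for oxidative phosphorylation 0.16 and for the unfolded protein and integrated stress responses 0.03. Medians of lists between 0 and 0.12 change sign when the ratios are centred. The Wnt antagonist Wif1 was 3.97-fold higher (2.72 to 5.96) and the ligand Wnt4 4.28-fold lower (2.99 to 6.25).

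Several measures that depend on RNA quality and tissue handling differed between the libraries. Ribosomal RNA loci took 0.308% of reads with DMSO (Wilson interval 0.305% to 0.311%) and 0.654% with C3G (0.650% to 0.658%), while mitochondrial genes took 5.36% (5.35% to 5.37%) and 5.74% (5.73% to 5.75%). Immediate early and stress genes, which respond within minutes to handling as well as to growth signals, had a median of -0.45 (random range -0.20 to 0.21), with 6 of 20 lower and 2 higher by size. The median was -0.29 with length and GC trends removed, still below the random lists. After Hspa1a and Hspa1b, the largest ratios were those of Klf2, 3.24-fold lower (2.96 to 3.56), and Jun, 2.71-fold lower (2.64 to 2.78). The 2 higher members were Egr3 (12.3 against 30.0 TPM) and Ier3 (432 against 901 TPM). Mitochondrially encoded genes, with a median of -0.10, ribosomal protein genes, with a median of 0.04, and red blood cell genes, with a median of -0.13, lay inside their ranges.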

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

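Thinning to equal depth, removing length and GC trends, matching on length and requiring 50 reads were chosen after the data were seen. Leaving out centring, which cannot change a percentile, 406 of 421 values of list summaries under the alternatives gave the same call against the random range. In 25 of these 406 the sign differed from that of the main median, all in lists that lay inside their range. No paired analysis was possible because each group has 1 library.

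Genes higher and lower by size numbered 179 and 309 with a pseudocount of 5, 1086 and 1218 with no filter on low values, 109 and 241 with the stricter filter, 113 and 113 at a log2 ratio of 2, and 218 and 312 with at least 50 reads, each by the setting's own construction. The median log2 ratio of expressed genes was 0.114 with a pseudocount of 0.1, 0.0722 with 5, 0.0781 with no filter, 0.126 with the stricter filter, -0.0179 after centring and 0.110 after rescaling without mitochondrial and top genes. The correlation across genes was 0.879 with a pseudocount of 0.1, 0.966 with 5, 0.964 with no filter, 0.935 after that rescaling and 0.941 after thinning.

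For the list of aryl hydrocarbon receptor and xenobiotic genes the median was 0.463 with a pseudocount of 0.1, 0.370 with trends removed and 0.266 without Cyp2e1, no longer outside the range, and 0.0848 with no filter, which lay under the middle of its random lists. Skin genes no longer stood apart with no filter (-0.0259) or without Sprr1a (-0.572). Lists that came to stand apart were luminal epithelium by its mean (-0.290), immune checkpoints with no filter (-0.253), after rescaling without mitochondrial and top genes (-0.249), after thinning (-0.261) and with trends removed (-0.224), NF-kB with the stricter filter (-0.258), epithelial-mesenchymal transition with trends removed (-0.161), Wnt targets with the stricter filter (0.548) and Notch targets after thinning (0.385). Except where a member was left out, the cause was not tested. The rescaling without the milk, adipocyte, skeletal muscle, skin and red blood cell lists could not be run on those lists themselves. Also not run for lack of members were the stricter filter for skeletal muscle and neutrophils, and the rescaling without mitochondrial genes for those genes. Depth limited genes with few reads, such as most T cell genes.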

Other observations

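The gene groups here and in the next paragraph were chosen after the data were seen. Replication-dependent histone genes had a median log2 ratio of 0.58 over 42 measured genes (random range -0.15 to 0.27), with 11 higher and 1 lower by size. Transcripts of these genes mostly lack poly(A) tails, for which the library kit selects, and ribosomal RNA loci, another such class, took 0.654% of reads with C3G against 0.308% with DMSO. Genes of DNA replication and G1/S were higher in the same library too, with a median of 0.56. The linker histone gene Hist1h1e stood at 4.30 against 12.4 TPM, 2.89-fold higher (1.99 to 4.31), and Hist1h2ap and Hist1h1b lay among the genes with the highest ratios. The abundant members went the other way, with Hist1h1c at 345 against 291 TPM and Hist1h2bc at 238 against 177 TPM. The summed TPM of all 69 histone genes of this group in the table was therefore 768 in both tumors. The group was taken by gene symbol, and whether each member is replication-dependent was not checked. The member lower by size was Hist1h2ac, at 7.06 against 1.39 TPM. Acute phase genes lay inside their random range, with a median of 0.29, but 4 of 12 were higher and 2 lower by size. Orm1, haptoglobin (Hp, 52.6 against 152 TPM), the lipopolysaccharide-binding protein gene Lbp (28.3 against 65.2 TPM) and Saa3 (6.82 against 16.2 TPM) were higher, and the fibrinogen genes Fgb and Fgg were lower.

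Heat shock genes as a group had a median of -0.42 over 14 genes (random range -0.20 to 0.25), with 4 lower by size. Hspa1a and Hspa1b, also members of the immediate early list, were among them, and the others were the small heat shock genes Cryab, 3.44-fold lower (3.07 to 3.85), and Hspb1, 2.06-fold lower (1.94 to 2.18). Genes of the actin cytoskeleton and S100 proteins had a median of -0.52 over 15 genes (random range -0.28 to 0.21). The tropomyosin Tpm2 stood at 337 against 75.9 TPM, 4.44-fold lower (4.16 to 4.73), Myl9 was 2.41-fold lower (2.25 to 2.60) and S100a6 2.07-fold lower (1.95 to 2.19). In the library in which the heat shock, actin and S100 genes were lower, immediate early genes had a median of -0.45 and ribosomal RNA loci took 0.654% of reads against 0.308% with DMSO. Basal and myoepithelial genes were lower there too, with a median of -0.57. Of them, 5 genes known from smooth muscle contraction were lower by size. Circadian clock genes had a median of 0.30 over 17 genes, inside their random range of -0.09 to 0.36, with none called by size.

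All tests below, the second adipocyte list and the removal of length and GC trends included, were chosen after the data were seen. For the tests on a lymph node, on the share of non-epithelial cells, on the MHC locus, on length and GC content for immune genes and on the share of epithelial cells, the result itself had been seen as well. The first pattern was the higher level of adipocyte genes in the C3G library. A gene length and GC trend was argued against, because the adipocyte median was 1.33 with those trends removed and 1.34 before. More fat tissue in the C3G sample may account for the pattern. A second adipocyte list cannot tell that from higher expression of such genes per fat cell, because either would raise it. This list, which shares no gene with the first, had a median of 0.44 over 13 genes, above its random range of -0.21 to 0.39. That median was smaller than that of the first list, and its most abundant members moved little, with Pnpla2 at 121 against 136 TPM and Adig at 75.7 against 71.0 TPM. Whether any added fat came from the treatment, from that mouse or from the piece of tissue taken stays open and was not tested.

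The second pattern was the lower level of lymphocyte, MHC and interferon genes in the C3G library. A lower share of all non-epithelial cells would lower macrophage and fibroblast genes too. Their median was -0.028 (quartiles -0.23 and 0.12), with 15 above and 19 below 0. Lymphocyte genes had a median of -0.98 (quartiles -1.40 and -0.44). That argues against such a share as the whole account, although the values had been seen before the criterion was set. An allele difference or shared reads at the MHC locus cannot account for the MHC and interferon list members outside chromosome 17. Their median was -0.60 over 32 genes. For the H2 genes on chromosome 17 this test cannot decide, because other genes can be lower at the same time, and that explanation stays open for them. Length and GC content as the whole account were argued against by a median of -0.72 with those trends removed and -0.71 before, over 75 genes. Single lists moved more. With the trends removed the T cell median went from -0.91 to -0.74 and the cytotoxic median from -1.16 to -0.97, both still below their random lists. The MHC class I median was -0.74 before and -0.75 after. A lymph node in the DMSO sample stays open: 14 follicular B cell and lymph node genes, 3 of them with a mean TPM of at least 1, summed to 8.81 TPM there, 0.095 of the 92.6 TPM of T cell genes, but the B cell and plasma cell list summed to 142 TPM and the ratio in a lymph node was not measured. Treatment, differences between the individual mice and the region sampled also stay open with 1 tumor each, and none of them was tested.

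The third pattern was the higher level of cell cycle genes in the C3G library. A higher share of epithelial cells was argued against, since luminal genes had a median of -0.079 (quartiles -0.59 and 0.07) beside 0.70 for cell cycle genes (quartiles 0.55 and 0.92). Length and GC content were argued against by a median of 0.69 with those trends removed and 0.70 before, over 40 genes. Treatment, differences between the individual mice and the stage at which each tumor was taken stay open, and none of them was tested.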
